A study of Mus musculus with 4 samples.

How the data were processed

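Per the labels, total RNA of embryoid bodies harvested on day 7 went into standard Illumina libraries, and the selection of RNA is not given in the sources used here. There were 4 libraries, 2 Control and 2 Trim33-deficient, grouped by their titles. The labels give the Control genotype as wild type and do not state whether Control bodies received 4-hydroxytamoxifen. The submitters' processing notes name STAR, HTSeq, DESeq and the mouse build mm9, with no versions or roles. The deposited files hold raw counts per gene symbol, not normalised, for 24015 genes in each library. Rows that name no gene were kept out of library sizes and tests. Reads assigned to no feature made up 55.8%, 55.9%, 56.0% and 55.5% of the reads in the files in Control replicates 1 and 2 and Trim33-deficient replicates 1 and 2, and ambiguous reads at most 0.200%. The strand setting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The Rn45s ribosomal RNA gene took 1.87% to 2.29% of counts in genes.

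The authors' deposited table gives, per the file headers, the mean normalised signal of each gene (baseMean), a log2 fold change, a p-value and an adjusted p-value, for 84 genes whose highest adjusted p was 0.0496. Its design and dispersion settings are not given in the sources used here. Size-factor means were recomputed from the counts, with the rows that name no gene included when the size factors were estimated. They matched the log2 fold changes of the authors' deposited table within 0.00371, which set its direction as Trim33-deficient over Control.

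Genes were filtered with filterByExpr, which left 14259 genes, and scaled by TMM. They were tested with edgeR 4.0.16 (quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, two-sided and without a replicate block. Standard errors were the absolute log2 fold change divided by the square root of F. Levels are TMM-normalised CPM, and log2 CPM used a prior count of 2. Alternatives were DESeq2 1.42.0, edgeR's likelihood ratio test, limma 3.58.1 voom, other scalings, other filters, the block, other thresholds and each library left out. When a library is left out, the lone library of its group is assumed to vary like the other group. Such a fit also breaks 1 of the pairs taken by number. Ranges of a gene's log2 fold change over the left-out libraries cover the edgeR and the DESeq2 fits. GC content and length came from the longest GRCm38 transcript of each symbol, matched for 99.4% of tested genes, and their trend was removed by loess. Neighbouring genes were taken from the GRCm38 gene order and compared with 100000 random sets.

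Gene lists, 38 in all, the tests, the main alternatives and the rule for named genes were fixed before the data were examined. The 37 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and the list of 2-cell-like genes had fewer. No list passed with an estimated correlation, where the lowest adjusted p was 0.528, or with directional fry (lowest 0.0909). The test with an estimated correlation uses no more than the 2 residual degrees of freedom of the fit. A call lost with it need not reflect correlated members. Among called lists the estimated correlation ran from −0.0494 for unfolded protein and amino acid stress genes to 0.799 for neuroectoderm genes. Where it lies above the preset 0.01, the camera p at the preset can be too small. Mixed fry, which tests for change in either direction, passed visceral endoderm (0.0126), hypoxia and glycolysis (0.0130) and neural crest (0.0133). Named genes were Trim33 and up to 12 called genes per direction with a mean of at least 2 CPM and non-overlapping groups, filled to 8 by smallest p as values. To these were added the 4 members with the smallest p in each called list, 2 in other lists, and the 5 highest and lowest finite log2 fold changes of the authors' deposited table at adjusted p under 0.1. Not every gene that this rule names is given.

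The labels speak of independent pairs and the replicate number is the only label that tells pairs apart, so numbers were taken as pairs and the fit with the replicate number as a block was run beside the fit without it, which was the main one because the authors' design is not given. Members on the same side within both pairs were counted after the results were seen. Deviations from the group means of same-numbered libraries correlated across genes (Pearson 0.236, Spearman 0.207). Replicates were not duplicate deposits, since the chi-square per degree of freedom between them was 35.7 for Control and 24.3 for Trim33-deficient libraries. The labels do not say that replicates came from separate cell lines, so p-values measure the spread between these libraries.

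The tests were tested on simulated data for the Trim33-deficient against Control comparison, with 14259 genes and 50 genes changed at each fold. With dispersions on a trend, the quasi-likelihood test recovered 34% of 2-fold and 94% of 4-fold changes with 3 false calls. DESeq2 then made 5 false among 171 calls and the likelihood ratio test 3 among 165. A further setting was added after the first simulation results had been seen. It scattered the dispersions about the trend by the prior degrees of freedom that the quasi-likelihood fit estimated (2.67). There the quasi-likelihood test recovered 0% of 2-fold, 16% of 4-fold, 54% of 16-fold and 82% of 64-fold changes, with 3 false among 79 calls. In that setting DESeq2 recovered 78% of 4-fold changes with 152 false among 304 calls, and the likelihood ratio test 64% with 94 false among 231. Lists were simulated with dispersions on the trend only. There camera called the 1 list shifted by 0.6 log2 units and no other, while the estimated correlation gave that list an adjusted p of 0.992. Directional fry missed it (adjusted p = 0.191), and mixed fry called 3 lists, the shifted list among them, although 1 was shifted. Genes of the simulation vary independently, which the real genes of a list need not do.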

Results

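RNA was sequenced from mouse embryoid bodies, the free-floating aggregates in which embryonic stem cells differentiate. Per the labels, the stem cells were homozygous for a floxed Trim33 allele and carried UbcCreERT2, a Cre recombinase switched on by tamoxifen. Trim33 encodes a chromatin-binding ubiquitin ligase of the TIF1 family that partners with SMAD proteins. Deficiency was induced with 4-hydroxytamoxifen on day 4 and the bodies were harvested on day 7. There were 2 Control and 2 Trim33-deficient libraries. The labels give the genotype of the Control libraries as wild type, so whether Control bodies carried the floxed allele and Cre is not settled by them. The libraries are described there as independent pairs. The 2 Control libraries held 12390541 and 10422738 counts in genes, and the 2 Trim33-deficient libraries 13808837 and 12109547. Control replicate 1 stood apart, with Pearson correlations across genes of 0.932 to 0.952 with the other libraries, against 0.967 to 0.978 among those others. Genes are not independent replicates, so these coefficients only describe the libraries.

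The targeted gene was examined first. Trim33 had 1203 and 1117 counts in the Control libraries and 608 and 495 in the Trim33-deficient libraries. Its normalised level was 101 ± 11.4 CPM in Control and 43.1 ± 1.11 CPM in Trim33-deficient bodies (SD, n = 2 each), so 42.6% was left. The log2 fold change was −1.23 with a standard error of 0.13, and both Trim33-deficient libraries lay below both Control libraries. The edgeR quasi-likelihood test did not call it (adjusted p = 0.219), whereas DESeq2 did (adjusted p = 6.9e-06). The DESeq2 call for the Trim33 level was lost without Trim33-deficient replicate 1 or 2 (DESeq2 adjusted p = 0.232 and 0.277). The position of the floxed exons was not used here, so transcripts that lack them can still be counted.

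The series asks which genes differ between Control and Trim33-deficient embryoid bodies. Apoc2, an apolipoprotein of triglyceride-rich particles, fell from 60.5 ± 0.837 to 0.860 ± 0.00806 CPM (SD, n = 2 each), a 69.5-fold lower level. Cubn, which encodes the endocytic receptor cubilin, fell from 120.3 ± 12.3 to 4.45 ± 0.475 CPM (SD, n = 2 each), 27.0-fold lower. Their log2 fold changes were −6.12 (SE 0.18) and −4.76 (SE 0.17), with edgeR quasi-likelihood adjusted p = 0.0138 and 0.0166. These were the only 2 genes that the test called lower among 14259 genes, and it called 0 higher. At an unadjusted p under 0.05 there were 682 lower and 436 higher genes, 1118 in all against 713 expected by chance. DESeq2 called 113 lower and 23 higher, edgeR's likelihood ratio test 140 and 29, and limma voom 0 in either direction. The 2 groups did not overlap for 40.7% of genes, where chance gives 33.3%. The edgeR counts depended on single libraries. Without Control replicate 1 there were 10 calls, all lower, and without Control replicate 2 there were 66 lower and 25 higher, and both genes were among them. Without Trim33-deficient replicate 1 or 2 edgeR called 0, and its adjusted p for both genes was then 0.835 or 0.826. The folds barely moved, with Apoc2 from −6.13 to −6.11 and Cubn from −4.87 to −4.63 over all left-out libraries. DESeq2 kept both calls in these fits, with adjusted p of 5.4e-19 and 1.6e-21 for Apoc2 and 2.1e-23 and 3.2e-27 for Cubn.

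Among genes that did not pass, those with the smallest p in the lower direction were secreted and absorptive products of endoderm. Afp, the alpha-fetoprotein gene, had 4985 and 2645 counts in the Control libraries and 139 and 141 in the Trim33-deficient libraries. Its log2 fold change was −4.87 (SE 0.27, edgeR adjusted p = 0.0801). Trf, Apob, Apoa1, Amn and Apoa4, encoding transferrin, 3 apolipoproteins and the cubilin partner amnionless, had log2 fold changes of −3.62, −4.33, −4.16, −4.30 and −5.40. Their edgeR adjusted p ran from 0.0853 to 0.164. In the higher direction the values were 3.91 for the keratin gene Krt79, 3.49 for Nipal1, 3.47 for the cornified envelope gene Sprr1a, 1.23 for Nfxl1 and 1.23 for Cd44. The lipid genes Sqle and Aacs had 0.83 and 0.80. The edgeR adjusted p of these 7 genes lay between 0.252 and 0.326. In the Control libraries Krt79 had 9 and 2 counts and Sprr1a 4 and 5, so their folds are imprecise, and Krt79 ranged from 3.33 without Control replicate 2 to 5.17 without Control replicate 1.

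**Figure D1:**
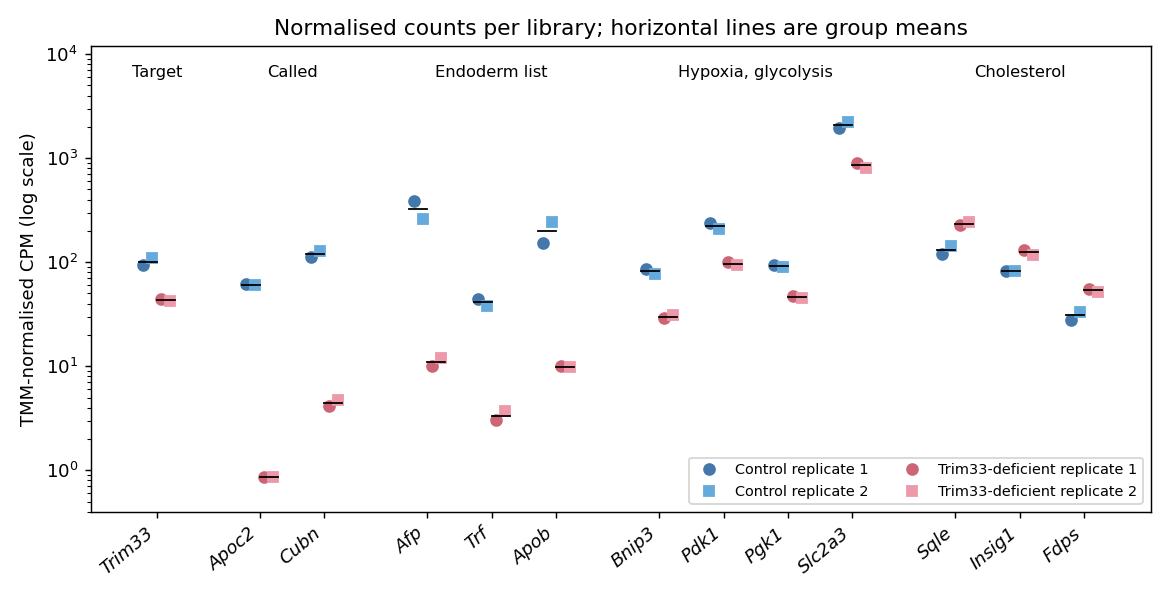
TMM-normalised CPM (log scale) of named genes in each of the 4 libraries, with horizontal lines at the group means of 2 libraries. Cubn falls from a mean of 120.3 to 4.45 CPM, while Sqle lies at 132 in Control and 235 in Trim33-deficient bodies.

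Visceral and extraembryonic endoderm markers fell as a group. Of 23 members tested, 21 had a log2 fold change below 0, with a median of −2.45. In 18, both Trim33-deficient libraries lay below both Control libraries, as they did for 3049 of all 14259 genes tested. Chance parts the groups either way for 33.3% of genes. Adjusted over the list alone, 16 members fell, and over all genes tested 1 did, Cubn. Within both pairs taken by number, 18 of 23 members were lower and 2 higher. Camera with its preset correlation gave an adjusted p of 8.3e-18, but adjusted p = 0.528 with an estimated correlation. Leaving out each library in turn kept the camera call, with adjusted p from 4.9e-20 to 1.7e-09. The basement membrane members did not share this size. Lama1, Lamb1, Col4a1, Col4a2 and Sparc, which encode laminin chains, type IV collagen chains and osteonectin, had log2 fold changes from −0.21 to 0.29. These 5 genes were singled out after their values were seen.

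Hypoxia-inducible and glycolytic genes fell together as well. All 19 members tested had log2 fold changes below 0, with a median of −0.89, and adjusted over the list alone 13 fell, against 0 over all genes tested. Within both pairs taken by number, 17 of 19 were lower. Bnip3, a mitophagy receptor, was at −1.44 (SE 0.13), the glucose transporter gene Slc2a3 at −1.30 (SE 0.16) and the pyruvate dehydrogenase kinase gene Pdk1 at −1.21 (SE 0.12). The glycolytic enzyme gene Pgk1 was at 92.1 ± 2.02 CPM in Control and 46.0 ± 1.60 CPM in Trim33-deficient bodies (SD, n = 2 each). Camera gave an adjusted p of 1.6e-14, and adjusted p = 0.528 with an estimated correlation. That correlation was 0.0124, near the preset 0.01, so correlated members do not account for the difference in this list. Leaving out each library in turn kept the camera call (adjusted p from 8.0e-15 to 1.1e-08). Gapdh, a member, was counted at a mean of 3.12 CPM, a level at which reads shared with its many pseudogenes can be missing.

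Genes of cholesterol synthesis rose as a group. All 17 members tested were above 0, with a median of 0.60, and adjusted over the list alone 12 rose, against 0 over all genes tested. Within both pairs taken by number, 16 of 17 were higher. The squalene epoxidase gene Sqle was at 0.83 (SE 0.13), the sterol sensor partner Insig1 at 0.60 (SE 0.11) and the prenyl synthase gene Fdps at 0.80 (SE 0.15). The camera adjusted p was 7.1e-11, with adjusted p = 0.712 with an estimated correlation, and it stayed between 1.8e-10 and 3.7e-06 as each library was left out.

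A further 3 lists kept their camera calls without any single library. Targets of p53 rose, with 19 of 21 members above 0 and a median of 0.24 (camera adjusted p = 2.4e-05). Plk2 had a log2 fold change of 0.78, Trp53inp1 0.60, Phlda3 0.57 and Cdkn1a, the p21 gene, 0.53. Cytoplasmic ribosomal protein genes fell, with 24 of 27 below 0 and a median of −0.25 (camera adjusted p = 2.4e-05). Rpl3 was at −0.46, Rpl37 at −0.32, and Rps2, with 4.59 CPM on average, at −1.19. Rpl3 and Rpl37 averaged 58.2 and 56.8 CPM. Whether reads shared with pseudogenes are missing here, as they can be for Gapdh, was not tested. Pluripotency genes fell, with 21 of 23 below 0 and a median of −0.64 (camera adjusted p = 0.000102). The transcription factor genes Tfcp2l1, Nanog and Sall4 were at −0.92, −0.95 and −0.57, and Tdh, encoding threonine dehydrogenase, at −1.25. Adjusted over the list alone, 1 pluripotency gene fell and 0 of the other 2 lists changed. All 3 had adjusted p = 0.712 with an estimated correlation. Within both pairs taken by number, 15 of 21 p53 targets were higher. Of ribosomal protein and pluripotency genes, 21 of 27 and 11 of 23 were lower in both pairs. The camera adjusted p with the replicate block was 0.000105, 0.000246 and 0.000497 for p53, ribosomal and pluripotency genes. As libraries were left out, the highest camera adjusted p was 0.0420 for p53 targets, 0.0412 for ribosomal protein genes and 0.0303 for pluripotency genes, the first 2 without Control replicate 2 and the last without Control replicate 1.

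Heart, mesenchyme and HOX lists rose, with calls that were lost or turned in unpaired fits without some single libraries. Within the pairs taken by number, 16 of 17 smooth muscle and fibroblast genes and 18 of 26 HOX genes were higher in Trim33-deficient bodies in both pairs, against 5 of 19 cardiomyocyte and 6 of 19 cardiac progenitor genes. With the replicate block the camera adjusted p was 6.7e-09, 3.4e-06, 0.00216 and 0.00292 for these 4 lists. Cardiomyocyte contractile genes had 18 of 19 members above 0 and a median of 1.45 (camera adjusted p = 0.000566). The natriuretic peptide genes Nppa and Nppb were at 2.42 and 1.94, Ankrd1 at 2.02 and the tropomyosin gene Tpm1 at 0.68. These genes are among the 5 of 19 members with both Trim33-deficient libraries above both Control libraries. They do not stand for the list, most of whose members disagreed in direction between the pairs. Ankrd1 ranged from 1.32 without Control replicate 1 to 3.37 without Control replicate 2, Nppa from 1.98 to 3.01 between the same fits, and Nppb from 1.51 without Control replicate 2 to 2.64 without Control replicate 1. Without Trim33-deficient replicate 1 the camera adjusted p was 0.893. Cardiac progenitor genes had 18 of 19 above 0 and a median of 0.48 (camera adjusted p = 0.00844), with Nkx2-5 at 1.88, Hcn4 at 1.15, Bmp2 at 0.89 and Smarcd3 at 0.52. Nkx2-5 had 656 counts in Trim33-deficient replicate 1 and 55 in replicate 2, against 59 and 99 in Control. From the fits without Control replicate 1 to those without Control replicate 2, with edgeR or DESeq2, Hcn4 ranged from 0.57 to 2.11, Bmp2 from 0.35 to 1.78 and Smarcd3 from 0.079 to 1.14. The cardiac progenitor call was lost without Trim33-deficient replicate 1 (camera adjusted p = 0.298), and without Control replicate 1 the direction turned (0.703). Smooth muscle and fibroblast genes had 17 of 17 above 0 and a median of 0.83 (camera adjusted p = 0.000265), with Thy1 at 1.03, Cnn1 at 0.83, Tagln at 0.93 and Myh11 at 1.46. Tagln ranged from 0.51 without Trim33-deficient replicate 2 to 1.41 without Control replicate 2, and Myh11 from 0.93 to 2.16 between the same fits. The smooth muscle call was lost without Control replicate 1 (0.532) or Trim33-deficient replicate 2 (0.0591). HOX genes had 22 of 26 above 0 and a median of 0.71 (camera adjusted p = 0.000526), with Hoxb6 at 1.76, Hoxb9 at 1.01 and Hoxa5 at 0.88 but Hoxd1 at −1.20. Hoxb6, with 5 and 32 counts in Control, ranged from 0.89 without Control replicate 1 to 3.94 without Control replicate 2. Without Control replicate 1 the HOX direction turned (camera adjusted p = 0.876). In each of these 4 lists 0 members passed adjusted over the list alone, and adjusted p = 0.712 with an estimated correlation.

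Lists of early germ layer and germline genes fell, with calls that were lost in unpaired fits without some single libraries. Within both pairs, 15 of 22 neuroectoderm, 5 of 13 germline, 7 of 12 primitive streak and 9 of 18 definitive endoderm genes were lower. With the replicate block the camera adjusted p was 3.4e-06, 0.0257, 0.0126 and 0.0276 for these 4 lists. Neuroectoderm genes had 19 of 22 below 0 and a median of −1.03 (camera adjusted p = 0.00605), with Nkx2-2 at −2.18, Otx2 at −1.49 and Olig2 at −1.42. Otx2 had 1903 and 506 counts in Control, and its value was −0.50 without Control replicate 1 and −2.06 without Control replicate 2. Nkx2-2 ranged from −3.60 without Trim33-deficient replicate 1 to −1.34 without Control replicate 1, and Olig2 from −1.80 to −0.88 over the left-out libraries. Without Control replicate 1 or Trim33-deficient replicate 2 the camera adjusted p was 0.876 or 0.457. Germline genes had 12 of 13 below 0 and a median of −0.99 (camera adjusted p = 0.0102), with Prdm14 at −1.38, Nanos3 at −1.29, Dppa3 at −1.28 and Dnd1 at −0.97. The libraries that ended the neuroectoderm call ended this one too (0.963 and 0.0513). Prdm14 and Dppa3 also belong to the pluripotency list. Over the left-out libraries Prdm14 ranged from −1.89 without Control replicate 2 to −0.54 without Control replicate 1. Nanos3 ranged from −1.89 without Trim33-deficient replicate 1 to −0.91 without replicate 2, Dppa3 from −1.76 without replicate 2 to −0.89 without replicate 1, and Dnd1 from −1.45 without Trim33-deficient replicate 2 to −0.47 without Control replicate 1. The stricter low-count filter left the germline list fewer than 5 tested members, so it was not tested with that filter. Primitive streak genes had 8 of 12 below 0 and a median of −0.32 (camera adjusted p = 0.0273), with Mixl1 at −2.79, Tbx6 at −1.74, Wnt3a at −0.89 and Wnt3 at −0.75. Mixl1 had 16 and 11 counts in Control and 1 and 3 in Trim33-deficient libraries, and ranged from −4.00 without Trim33-deficient replicate 2 to −2.12 without replicate 1. From the fits without Control replicate 2 to those without Control replicate 1, Wnt3 ranged from −1.13 to −0.23 and Wnt3a from −1.42 to 0.0094. The primitive streak list missed the threshold with a stricter low-count filter (camera adjusted p = 0.273), and without Control replicate 1 (0.0749) or Trim33-deficient replicate 2 (0.598). Definitive endoderm and gut genes had 12 of 18 below 0 and a median of −0.40 (camera adjusted p = 0.0141). The liver and gut transcription factor gene Hnf4a was at −2.48 and Trh at −0.77, while Sox9 was at 0.67. Adjusted over the list alone 3 members fell, and Hnf4a also belongs to the visceral endoderm list. The call was lost without Control replicate 2 (camera adjusted p = 0.393) or Trim33-deficient replicate 2 (0.198). In the other 3 lists 0 members passed adjusted over the list alone, and all 4 had adjusted p = 0.712 with an estimated correlation.

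The remaining 6 called lists hold signalling targets and genes of proliferation, imprinting and stress. Within both pairs taken by number, 9 of 14 Hedgehog and Notch targets and 17 of 25 cell cycle genes were lower. Higher in both pairs were 2 of 13 FGF, 13 of 24 imprinted, 10 of 18 stress and 10 of 20 interferon genes. Most FGF genes thus disagreed in direction between the pairs. Hedgehog and Notch targets had 14 of 14 below 0 and a median of −0.27 (camera adjusted p = 0.00174), with Gli1 at −2.03, Hes5 at −1.79, Nrarp at −1.25 and Hhip at −1.10. Gli1 ranged from −2.79 without Trim33-deficient replicate 1 to −1.53 without replicate 2, and Nrarp from −1.95 to −0.78 between the same fits. Hes5 ranged from −2.82 without Trim33-deficient replicate 1 to −1.02 without Control replicate 1, and Hhip from −1.51 without Trim33-deficient replicate 1 to −0.54 without Control replicate 2. For the list, without Control replicate 2 or Trim33-deficient replicate 2 the camera adjusted p was 0.132 or 0.147. Cell cycle genes had 22 of 25 below 0 and a median of −0.16 (camera adjusted p = 0.0141), with Aurkb at −0.38, Ccnb2 at −0.33 and Bub1 at −0.29 but Tyms at 0.38. The libraries that ended the Hedgehog and Notch call ended this one too (0.260 and 0.588). The FGF feedback genes Spry4 and Il17rd were at 0.50 and 0.37 but did not rise in the pair numbered 2. There Spry4 was at 14.4 CPM in Control and 14.3 in Trim33-deficient bodies, and Il17rd at 58.5 and 57.6. As a list, FGF feedback genes had 12 of 13 above 0 and a median of 0.25 (camera adjusted p = 0.0189), with Dusp4 at 0.95 and Etv4 at 0.72. They missed the threshold without Control replicate 1 (0.630) or Trim33-deficient replicate 1 (0.893). Imprinted genes had 18 of 24 above 0 and a median of 0.25 (camera adjusted p = 0.0279), with Igf2r at 0.74, Ndn at 0.61, Grb10 at 0.43 and Impact at 0.29. That call was lost without Control replicate 1 (0.659) or Trim33-deficient replicate 2 (0.588). Unfolded protein and amino acid stress genes had 15 of 18 above 0 and a median of 0.18 (camera adjusted p = 0.0343), with Atf3 at 0.83, Trib3 at 0.59 and Atf4 at 0.38 but Ddit4 at −0.88. That call was lost with the replicate block (0.0542), and without either Control library or Trim33-deficient replicate 1 (0.105, 0.129 and 0.340). Interferon genes had 13 of 20 above 0 and a median of 0.17 (camera adjusted p = 0.0490), with Isg15 at 1.17, Gbp2 at 0.94 and B2m at 0.53 but Bst2 at −0.88. Isg15 ranged from 0.78 without Control replicate 2 to 1.80 without Control replicate 1. Without Control replicate 2 the list's direction turned (0.993), and without Trim33-deficient replicate 2 it missed the threshold (0.863). It also missed it with DESeq2 size factors (0.0539), voom weights (0.124) and a stricter filter (0.333). Adjusted over the list alone, Dusp4 passed in the FGF list, Atf3 and Ddit4 passed in opposite directions in the stress list, and 0 passed in the others. All 6 had adjusted p = 0.712 with an estimated correlation.

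**Figure D2:**
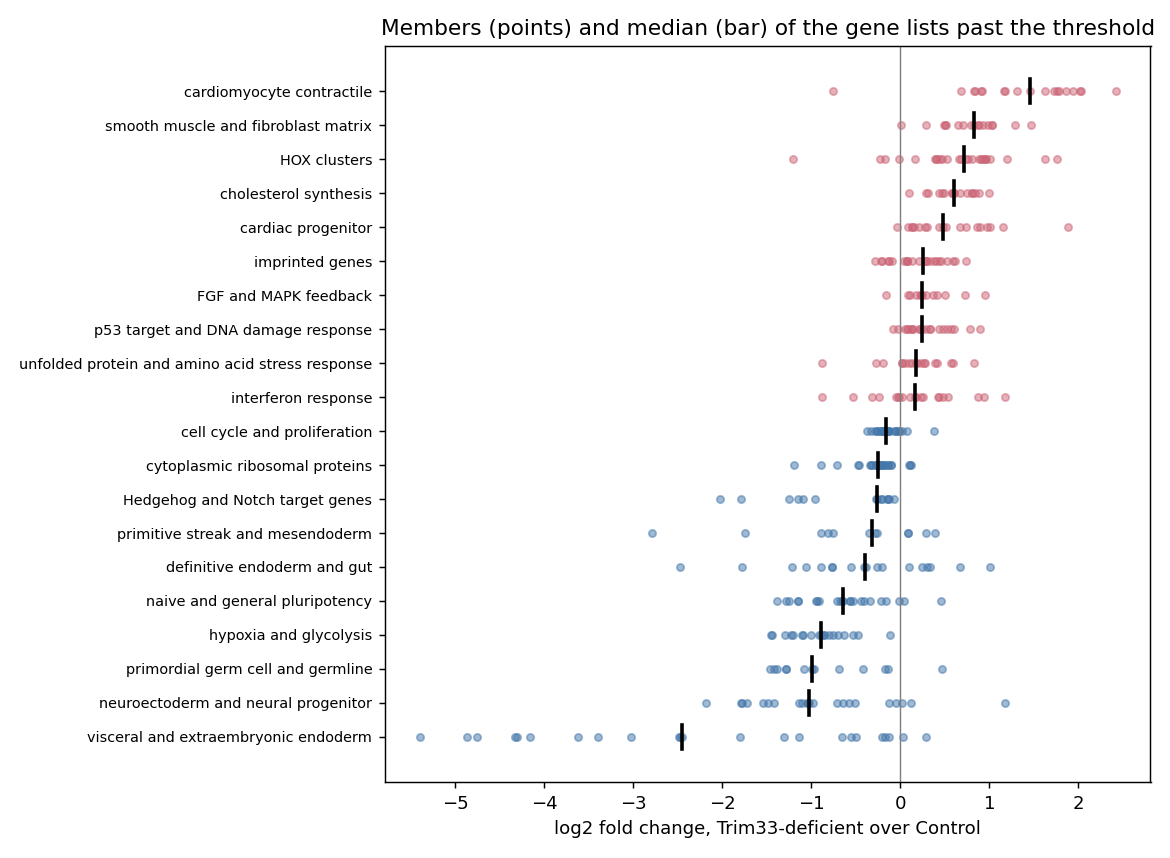
Log2 fold change of every tested member (points) of the 20 gene lists past the camera threshold, Trim33-deficient over Control, with a bar at each list's median. Medians run from −2.45 for visceral and extraembryonic endoderm to 1.45 for cardiomyocyte contractile genes. Of the latter, 5 of 19 were higher in both pairs taken by number.

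The other 17 of the 37 lists tested did not pass. Targets of Nodal and TGF-beta, a pathway in which TRIM33 acts with SMADs, had a median of 0.50 and 13 of 19 members above 0 (camera adjusted p = 0.0530). Ctgf was at 0.93 and Mixl1 at −2.79. With the replicate block, which pairs libraries by number, this list passed (camera adjusted p = 0.0212). So did hematopoietic genes, at 0.0917 without the block and 0.00904 with it, and WNT targets, at 0.106 and 0.0288. In the fit without the block, these 3 lists had adjusted p = 0.712, 0.712 and 0.752 with an estimated correlation. Runx1 and Cd34 were at 1.22 and 0.90, and the WNT targets Nkd1 and Lef1 at −0.57 and 0.43. Cd34 ranged from 0.39 without Control replicate 1 to 1.66 without Control replicate 2. Partners and relatives of TRIM33 had a median of 0.09 (camera adjusted p = 0.450), with Trim24 at 0.24 and Smad2 at 0.13. BMP targets had a camera adjusted p of 0.579, with Grem1 at 1.58 and Nog at −0.62. Camera adjusted p was 0.289 for macrophage genes, 0.294 for primed epiblast genes and for immediate early genes, 0.312 for surface ectoderm, 0.380 for neural crest and 0.560 for neuronal genes. It was 0.619 for chromatin silencing genes, 0.682 for paraxial mesoderm, 0.835 for endothelial and for estrogen and tamoxifen response genes, 0.855 for oxidative phosphorylation and 0.995 for trophoblast genes. The median, mean and camera direction differed in sign for the neural crest, BMP, endothelial, estrogen and oxidative phosphorylation lists. Some of these calls turned on single libraries. Without Control replicate 1 the camera test called endothelial genes lower (2.7e-05), and neuronal and trophoblast genes higher (3.1e-07 and 0.0196). Without Control replicate 2 it called the same lists in the opposite directions (2.1e-05, 5.4e-08 and 0.00450). Without Control replicate 2 or Trim33-deficient replicate 1, Nodal (0.0113 and 0.0440), hematopoietic (0.000207 and 0.00252) and WNT targets (0.00450 and 0.00445) passed. Immediate early genes passed without Control replicate 1 (0.0495) or Trim33-deficient replicate 1 (0.0482). Nodal and hematopoietic genes also passed with voom weights (0.0140 and 0.0454) and with a stricter filter (0.000249 and 0.0446). Dlx1, a neural crest list member, was at 1.79 (SE 0.31), and Cited1, of the estrogen list, at −1.43 (SE 0.21), and each passed adjusted over its list alone.

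The authors' deposited table held 84 genes, 14 of them higher and 70 lower in Trim33-deficient bodies. In the authors' deposited table the 5 highest log2 fold changes were 3.99 for Krt79, 3.50 for Nipal1, 3.05 for Prl3b1, 2.15 for Shisa3 and 2.01 for Ankrd1. Among the 5 lowest finite ones in the authors' deposited table were −6.13 for Apoc2, −5.70 for the glucose transporter gene Slc2a2, −5.43 for Apoa4 and −5.32 for Spp2. Slc2a2 had 127 counts in Control and 3 in the Trim33-deficient libraries, a 46.3-fold lower level with an exact Clopper-Pearson 95% interval of 15.5 to 228 that covers counting error only, and Spp2 had 0 and 5 counts in the Trim33-deficient libraries. Prl3b1 belongs to the prolactin family, whose similar copies can share reads. Cdhr2, named after its values were seen, had an infinite fold in the authors' deposited table, with 41 and 48 counts in Control and 0 in both Trim33-deficient libraries. All 84 genes had the same direction in the edgeR fit and an unadjusted p under 0.05, but the edgeR quasi-likelihood test called 2 of them and DESeq2 80. The table came from the same libraries, so it is not independent evidence. It held 11 visceral endoderm genes and 8 hypoxia or glycolysis genes, all lower, and 3 cholesterol genes, all higher, while 57 of its genes were in none of the fixed lists. Left out in turn, the Control libraries moved the edgeR overlap to 8 and 29 genes, and either Trim33-deficient library moved it to 0.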

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

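The DESeq2 fits with the replicate block or with a library left out were chosen after seeing the data. Other scalings, either filter, DESeq2, the likelihood ratio test, the older quasi-likelihood fit and the block kept the calls of Apoc2 and Cubn, and voom did not (adjusted p = 0.184). All settings with all 4 libraries kept the sign of every named gene with a value. The cause of the changes below was not tested, except that leaving out a library leaves fewer samples. The Trim33 level passed under DESeq2 (−1.22), the likelihood ratio test (−1.23) and DESeq2 with the block (−1.21), and its log2 fold change ranged from −1.35 to −1.09 as libraries were left out. Higher calls numbered 23 with DESeq2, 29 with the likelihood ratio test and 75 with DESeq2 and the block. Lower calls numbered 14 with no filter, 113 with DESeq2, 140 with the likelihood ratio test, 0 with voom, 117 with DESeq2 and the block, and 4 at adjusted p under 0.1. As libraries were left out, edgeR gave 0 to 25 higher and 0 to 66 lower calls, and DESeq2 5 to 390 higher and 35 to 286 lower. In simulations 152 of 304 DESeq2 calls were false with scattered dispersions, and 5 of 171 with dispersions on the trend. DESeq2 made 136 calls in the data. The number of false calls also depends on how many genes truly change, which was set in the simulations and is not known for the data. These counts therefore cannot show which setting is nearer the data. Since the share of false calls in the data is not known, the larger DESeq2 counts cannot be read as counts of true changes. With the replicate block edgeR called 0 higher and 2 lower genes, the same genes. The overlap with the authors' deposited table was 80 genes under DESeq2, 4 at adjusted p under 0.1, and 0 to 29 as libraries were left out.

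Camera called 20 lists, 22 with the block, 0 with an estimated correlation, 0 with directional fry, 3 with mixed fry, 19 with DESeq2 size factors, 21 with voom weights, 19 with a stricter filter and 11 to 21 as libraries were left out. The calls held without each single library for 6 lists, those of visceral endoderm, hypoxia, cholesterol, p53, ribosomal and pluripotency genes. The block ended the call of the stress list, added those of Nodal, hematopoietic and WNT targets, and changed no other call. With it the camera adjusted p was lower for smooth muscle (6.7e-09), HOX and neuroectoderm genes (both 3.4e-06) than for p53, ribosomal and pluripotency genes. Fits without 1 library break a pair, so they do not rank lists by agreement within pairs. Some lists turned direction when a library was left out. Their adjusted p over the left-out libraries ranged from 1.2e-11 to 0.876 for HOX genes, 5.2e-09 to 0.703 for cardiac progenitor, 0.00169 to 0.993 for interferon, 2.1e-05 to 0.618 for endothelial, 5.4e-08 to 0.863 for neuronal and 0.00450 to 0.960 for trophoblast genes. The ranges were 0.000207 to 0.983 for hematopoietic, 0.176 to 0.900 for TRIM33 partner, 0.0857 to 0.893 for BMP, 0.101 to 0.876 for surface ectoderm, 0.498 to 0.970 for chromatin and 0.192 to 0.923 for macrophage genes. Paraxial mesoderm ranged from 0.298 to 0.900 and also turned with a stricter filter (0.420). Estrogen response ranged from 0.802 to 0.970 and also turned with the block (0.816). Of named genes, 27 had log2 fold changes that ranged over more than 1 unit as libraries were left out, 0 of them among those edgeR called, and 5 changed sign. The latter ranged from −0.59 to 2.74 for Nkx2-5, −1.42 to 0.0094 for Wnt3a, −0.94 to 0.28 for Cd68, −0.14 to 1.18 for Isl1 and −2.34 to 0.0468 for Ascl2.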

Other observations

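As a check of the cell lines, Xist had 35 and 18 counts in the Control libraries and 30 and 18 in the Trim33-deficient libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 4 libraries, so the check did not separate the groups. It cannot show that the groups came from the same line.

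The tests below were chosen after the results were seen, except those on GC content and length and on the Nfxl1 and Nipal1 neighbourhood, and the GC content and length test was moved to the fit with the replicate block after its first result was seen. The lower visceral endoderm genes did not come from 1 control library alone, since the weakest of the 4 median log2 differences between a Trim33-deficient and a Control library was −1.87. Removing a trend on GC content and transcript length, in the fit with the replicate block, left the list median at −2.32, from −2.41. Whether there were fewer visceral endoderm cells, or less transcript in each, cannot be told apart here, since no level per cell was measured and other cells may supply what remained. The falls of 15 members differed by up to 4.26 log2 units, but these members were picked for at least 10 CPM in Control and a log2 fold change below −1, so their spread decides nothing. Apoe still had a mean of 268 CPM in Trim33-deficient bodies, and an effect of Trim33 loss itself stays open.

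The lower hypoxia and glycolysis genes and the higher sterol genes also held against each control library, with weakest median log2 differences of −0.779 and 0.417. After the GC content and length trend was removed their medians were −0.79 and 0.641. The hypoxia and glycolysis list lost 4166 CPM in sum, 2.38 times the 1753 CPM that the endoderm list lost outside its basement membrane members. No endoderm cells were measured apart, so transcripts carried by lost endoderm cells may account for part of this. The list's median of −0.886 also cannot be told apart from an effect of 4-hydroxytamoxifen or Cre activity, since the labels do not state the treatment of Control bodies. Nor can it be told apart from a difference between stem cell lines, since the labels give the Control genotype as wild type. Both limits hold for every comparison in the series, that of the visceral endoderm genes included.

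Nfxl1 and Nipal1 lie near each other in the GRCm38 gene order and were both among the higher genes with the smallest p. The other tested genes within 5 positions had a median log2 fold change of 0.0688, which argues against a change along the whole neighbourhood. Gm5868 between them was at 1.80 (SE 1.22) and Corin beside them at 0.95 (SE 0.76), named after their values were seen. A change limited to the nearest genes stays open. Among the 50 higher genes with the smallest p this was the only pair within 5 positions, where random sets of 50 tested genes gave 0.852 on average (permutation p = 0.577). With 1 pair so near the random average, the test could not tell a real pair from a chance one. A chance neighbour stays a candidate explanation for the pair.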
